A study of Homo sapiens and Mus musculus with 27 samples.

How the data were processed

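CHD7, FLAG and histone mark immunoprecipitates were labelled with Cy5 and genomic DNA of the same cells with Cy3, per the labels, so that every ratio runs from immunoprecipitated to genomic DNA. The lowest correlation between a pair of mouse arrays was -0.24, between H3K4me1 and H3K9me3 in ES cells. The tables with probe positions in the probe names were taken as log2 ratios as deposited by the authors, from their range and their 2 decimals, since the base is not stated. The table of the 6-region array was taken as log10 ratios as deposited by the authors and converted to log2. Its many exact zeros and long decimals look like the ratio column of Agilent software, but the base is not stated there either, and the sample titles name HG18. Scanner, software, normalization and, for the tables with positions, the genome build are not given in the sources used here. The scale and centring of the deposited ratios also stay unknown. Medians as deposited were 0.04 for ES CHD7 replicate 2, 0.03 for NPC H3K4me2, 0.02 for ES H3K4me1 and H3K4me2, 0.01 for ES H3K4me3 and H3K9me3, NPC H3K4me1 and SH-SY5Y H3K4me2, and -0.02 for SH-SY5Y H3K4me1. On the 6-region array they were -0.0087 and -0.0090 for FLAG replicates 2 and 3 and -0.0035 for CHD7 antibody replicate 3, and 0 on all other arrays of the 4 tables. The series describes the CHD7 replicates as biological ones, and the single DLD1 array on the ENCODE design is what was analysed here.

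Each array was centred on its median over probes, with no loess or quantile step. Probes were gathered in windows of 500 bp with at least 3 probes, and the window value of an array was the median of its probes, with a median of 10 probes per window in the CHD7 tables and 8 in the table of SH-SY5Y marks. The 6-region array, which has no positions in its probe names, was used probe by probe. A mean per group with a shared spread was fitted with limma 3.58.1 in R 4.3.3 to the 5 mouse CHD7 arrays, to the 3 human CHD7 arrays of the ENCODE table and to the 6 arrays of the 6-region table. Moderated tests were adjusted by Benjamini-Hochberg. A site needed an adjusted p under 0.05 and a mean of at least 0.5, and adjoining windows were merged to regions. The change from ES cells to NPC was tested over windows called in either, and the difference between SH-SY5Y and DLD1 over windows called in SH-SY5Y or in the top 1% of DLD1. The regions or probes named are those with the highest mean ratio in each list and the largest difference in each direction, a rule that took the first 10 and, like the tests and, except where stated, the alternatives, was fixed before the data were examined, and the text gives some of these 10. No gene is named, because no annotation of the build of the files was used. Gene lists fixed for the case of such an annotation are therefore not reported.

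Mark levels at sites were set against 1000 circular shifts of the sites along the ordered units, and correlations were computed over units, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Both human tables with positions differ in their segment bounds. The marks of SH-SY5Y were therefore read only in 30 of 45 segments where one end matched within 1000 bp and the other within 10000 bp. In these, CHD7 and H3K4me2 correlated best with no shift in 29 segments and with a shift of 1 window in 1, out of shifts up to 10000 bp. In the other 15 segments no best shift was within 1 window, and those on chromosomes 1 and 9 shared too few windows for any value. Except on chromosome 22, their bounds lay further apart than the shifts tested, such as starts of 26730761 and 26924062 on chromosome 7. The lack of a match there was thus set by the bounds. The bounds and tolerances were chosen after seeing the tables. No coordinate was converted.

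The fits were tested on simulated ratios with the fitted spread and 100 units raised and 100 lowered by a known size. Simulated differences were tested over all units of a table, while the measured differences between cell types were tested over fewer windows. Of units raised by 0.75 the ES fit recovered 55% among 42045, the NPC fit 0%, and the SH-SY5Y fit 0% among 40271. Of units raised by 1.5 these recovered 100%, 99% and 98%. On the 6-region array of 43102 probes the FLAG fit recovered 26% at 1.5 and 84% at 3, and the CHD7 antibody fit 0% and 88%. The difference between SH-SY5Y and DLD1 was recovered in 0% at 1.5 and 99% at 3, and that between NPC and ES cells in 88% at 1.5. These shares depend on how many units are changed and are not limits of detection. No unit was called with the wrong sign. Replicate numbers were not taken to pair the samples. Alternatives were no centring, scaling by the median absolute deviation, windows of 1000 bp, single probes, other minimum ratios, trended and robust moderation, each replicate left out and replicate numbers as a block. Handling of exact zeros, the base of the logarithm, a running median of 5 probes, the level on an ES array at sites called without it, the test of SH-SY5Y against DLD1 over all windows, and the use of the top 1% of windows as the NPC list were added after seeing the data. So were the overlap of both antibodies, CHD7 sites in the top 1% of windows by a mark, profiles around regions, marks in windows that differed between SH-SY5Y and DLD1, levels at FLAG probes and levels in depleted windows.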

Results

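The data were 27 two-colour tiling arrays from chromatin immunoprecipitation (ChIP-chip) of CHD7, a chromatin remodelling enzyme of the chromodomain helicase family, and of methylated histone H3. H3K4me3 is known to mark active promoters, H3K4me1 to mark enhancers and regions flanking promoters, and H3K9me3 to mark heterochromatin. Of these arrays, 12 were from mouse cells and 15 from human cells. The mouse arrays held CHD7 in embryonic stem (ES) cells (n = 3) and in neural precursor cells (NPC) derived from them (n = 2), H3K4me1, H3K4me2 and H3K4me3 in both, and H3K9me3 in ES cells. The human arrays held CHD7 in SH-SY5Y neuroblastoma cells (n = 2) and in DLD1 colorectal carcinoma cells (n = 1) on an ENCODE array, the 3 H3K4 marks in SH-SY5Y on another array, and a smaller DLD1 array of 6 regions with the CHD7 antibody (n = 3), the FLAG antibody, against FLAG-tagged CHD7 per the sample titles (n = 3), and the 3 H3K4 marks. Each histone mark had 1 array per cell type, so mark levels carry no replicate error and no p-value. The number of arrays limits the precision of every value. Values are log2 ratios of immunoprecipitated over genomic DNA, and the windows were 500 bp long. Positions are those in the probe names, whose genome build is not given in the sources used here for the tables with positions, and no gene annotation was used.

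The first comparison asked where CHD7 lay in mouse ES cells. CHD7 was enriched in 604 of 42045 windows, which merged to 417 regions in 44 of the 55 tiled segments. Over these windows the median CHD7 ratio was 0.77 ± 0.12 (SD of array medians, n = 3). The region with the highest mean was on chromosome 9 from 78444501 to 78445000, at 1.93 ± 0.43 (SD, n = 3), with H3K4me2 at 2.10 and H3K4me3 at 0.43. A region on chromosome 7 from 100409001 to 100410000 had CHD7 at 1.85 ± 0.19 (SD, n = 3), H3K4me2 at 2.87 and H3K4me3 at 1.53. A region on chromosome 6 from 15653501 to 15654000 had CHD7 at 1.77 ± 0.24 (SD, n = 3) and H3K4me1 at 1.52, with H3K4me3 at 0.06. On chromosome 11 from 54158501 to 54159000, CHD7 stood at 1.73 ± 0.13 (SD, n = 3) and H3K4me3 at -0.02. Among the 10 regions with the highest CHD7 ratio, H3K4me2 was at least 0.5 in 10, H3K4me1 in 9, H3K4me3 in 2 and H3K9me3 in 0. The segment of chromosome 9 from 78432064 to 78565704 had the highest share of enriched windows, 33 of 207, and was chosen for the map on that share, after its values were seen.

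Calls used limma's moderated test with Benjamini-Hochberg adjustment and a mean log2 ratio of at least 0.5, which also placed 532 windows below genomic DNA. The count rested on single arrays: it was 95 without ES replicate 1, 986 without replicate 2 and 361 without replicate 3. Scaling the arrays to a common spread gave 541 enriched and 1170 depleted windows, and leaving out the centring gave 760 and 1452. Trended and robust moderation gave 740 enriched and 10 depleted windows, and the depleted windows numbered 24 without ES replicate 1 and 2140 with only the ES arrays in the fit.

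**Figure D1:**
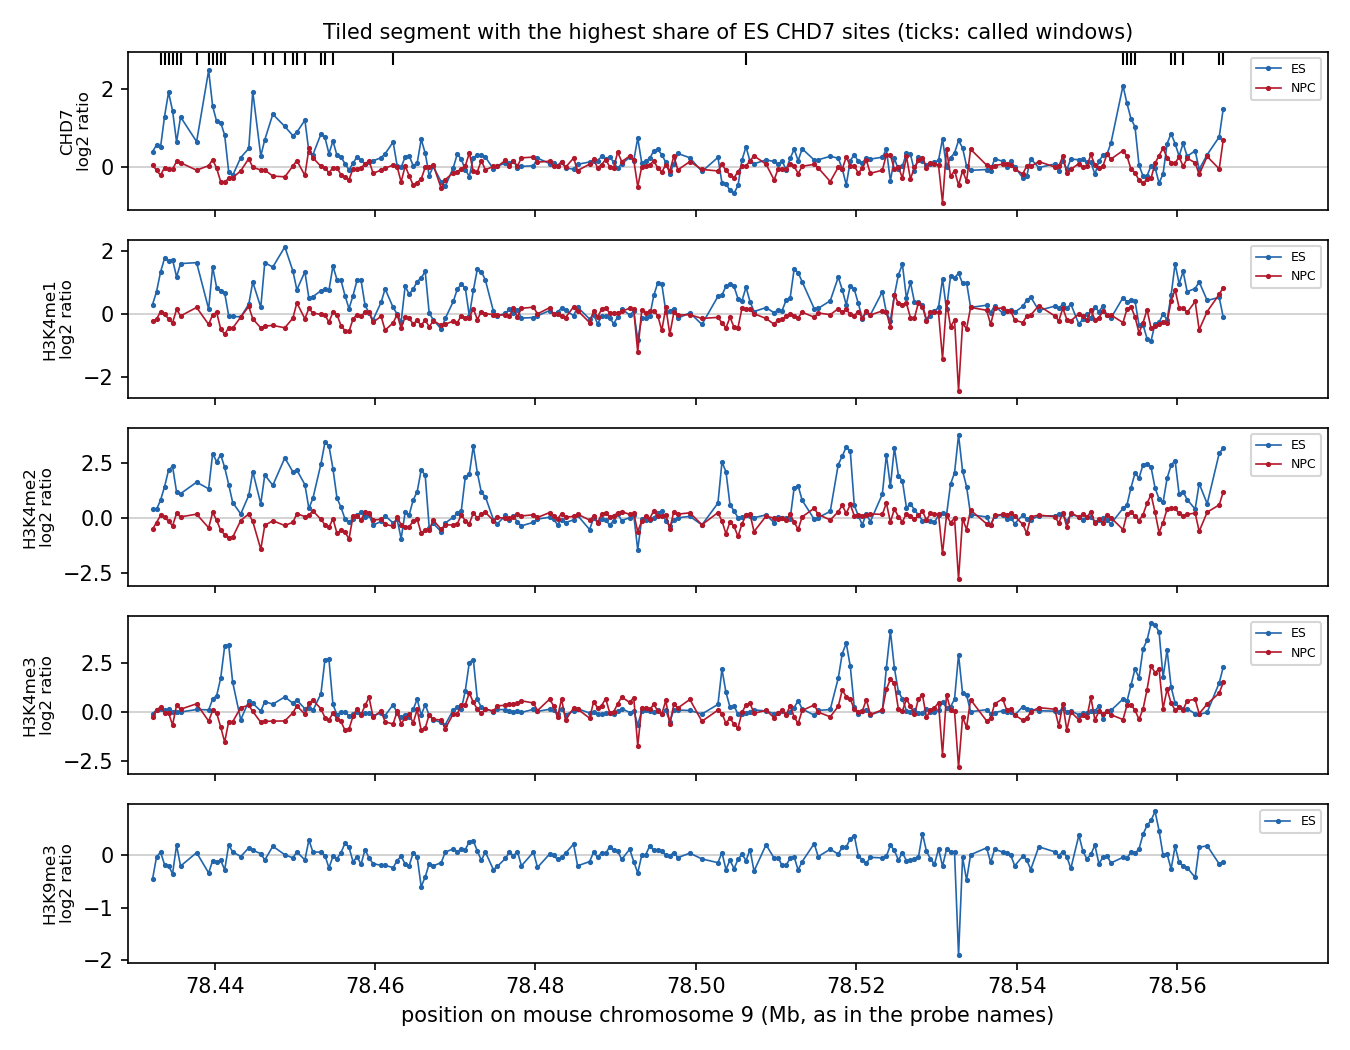
Log2 ratios of CHD7 (mean of 3 ES or 2 NPC arrays) and of each mark (1 array each) over 207 windows of 500 bp on mouse chromosome 9, against position in Mb; ticks mark the 33 windows called in ES cells. The ES line for CHD7 peaks at 2.47 in the window from 78439001 and at 2.08 in the window from 78553001, where the NPC line is at 0.04 and 0.42. NPC values of CHD7 lie between -0.91 and 0.69 over the segment.

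The marks at these ES sites were then compared with all other windows. H3K4me1 had a median of 1.15 at CHD7 sites and -0.03 elsewhere, a 2.26-fold difference, and H3K4me2 1.28 against -0.03, a 2.48-fold difference. H3K4me3 was at 0.19 against -0.01, a 1.15-fold difference, and H3K9me3 at -0.07 against 0. Of the sites, 97.7% lay above the table's median for H3K4me1, 83.3% for H3K4me3 and 30.1% for H3K9me3. Each H3K4 median exceeded all 1000 circular shifts of the sites along the tiled segments, and the H3K9me3 median lay below all of them. On the NPC arrays the H3K4me1 median at these sites, 0.13, also exceeded all shifts, while H3K4me2 exceeded 93.1% and H3K4me3 11.5%. Of the 604 sites, 265 (43.9%) had H3K4me1 in its top 5% without H3K4me3, against 3.58% of all windows. A further 118 (19.5%) had H3K4me3 in its top 5%, 49 (8.11%) had H3K4me2 alone and 172 (28.5%) had none of these. With means in place of medians the H3K4me3 difference was 0.35 in place of 0.20, and it was 0.36 for sites called without ES replicate 2. A CHD7 site was present in 20.8% of the top 1% of windows by H3K4me1, in 9.98% of those by H3K4me2 and in 1.90% of those by H3K4me3, against 1.44% of all windows. Of the top 1% of windows by H3K9me3, 10 of 421 held a CHD7 site, where independent lists would share 6.05 and the shifts shared up to 20.

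Across all ES windows, which are not independent replicates, CHD7 and H3K4me1 had r = 0.13 and rho = 0.15. The values were r = 0.10 and rho = 0.16 for H3K4me2, r = 0.02 and rho = 0.19 for H3K4me3, and r = 0.11 and rho = 0.20 for H3K9me3. These values rested on single arrays: without ES replicates 1, 2 and 3 in turn, r was 0.04, 0.40 and 0.04 for H3K4me1, 0.03, 0.42 and -0.05 for H3K4me2, -0.01, 0.28 and -0.13 for H3K4me3, and 0.15, 0.03 and 0.11 for H3K9me3. Without the top 1% of windows by CHD7, r was 0.06 for H3K4me1, 0.02 for H3K4me2 and -0.02 for H3K4me3. With the NPC arrays of the marks, the mean of the ES CHD7 arrays had r = 0.41 for H3K4me1, 0.59 for H3K4me2 and 0.50 for H3K4me3. That these exceed the r with the ES arrays of the marks depended on ES replicate 2 for H3K4me1 and H3K4me2. Without this replicate, r was 0.33, 0.35 and 0.34 with the NPC marks, beside 0.40, 0.42 and 0.28 with the ES marks. ES replicate 1 by itself ran the other way for each mark, with r of 0.06, 0.08 and -0.08 with the NPC marks and 0.37, 0.29 and 0.10 with the ES marks. Replicates 2 and 3 by themselves had the higher r with the NPC marks for each mark. For replicate 2 these were 0.37, 0.64 and 0.50, beside -0.12, -0.19 and -0.20 with the ES marks. For replicate 3 they were 0.44, 0.46 and 0.57, beside 0.30, 0.39 and 0.33.

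**Figure D2:**
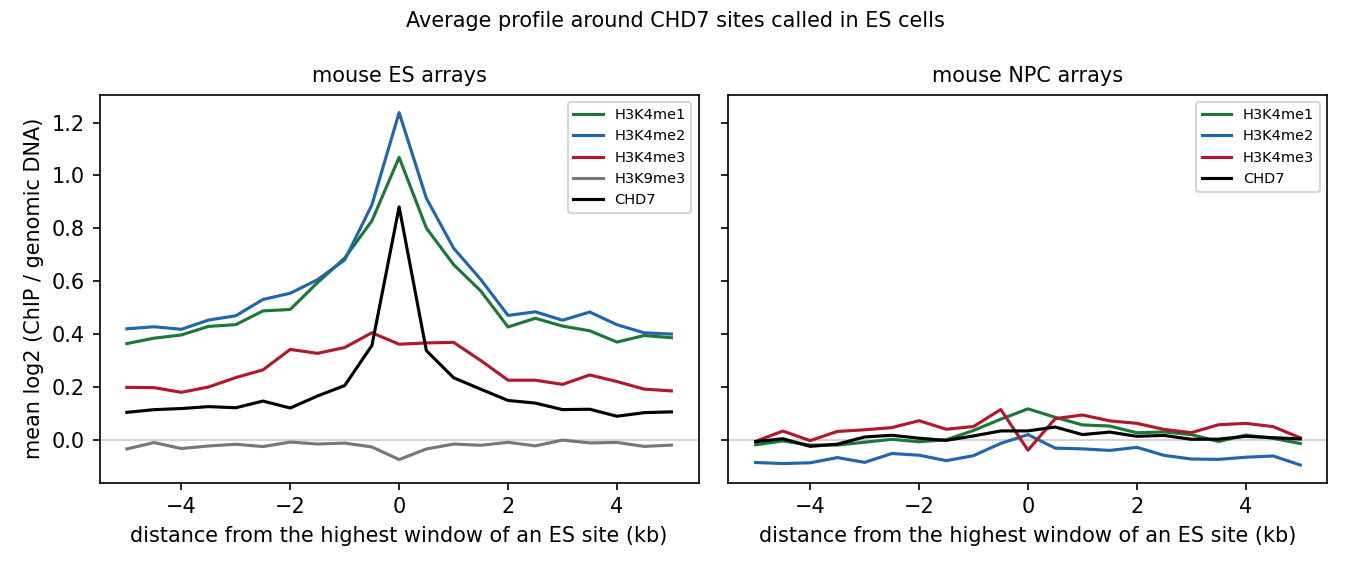
Mean log2 ratio of CHD7 and of each mark against the distance in kb from the highest window of each of 417 ES regions, on ES arrays (left) and NPC arrays (right), in steps of 500 bp. At the centre the ES means are 0.88 for CHD7, 1.07 for H3K4me1, 1.24 for H3K4me2 and 0.36 for H3K4me3, and the NPC means are 0.03, 0.12, 0.02 and -0.04.

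In NPC, no window was called as enriched for CHD7 with limma after adjustment, while 1548 of 42045 windows had an unadjusted p under 0.05. The 421 windows in the top 1% by CHD7 had a median ratio of 0.52 ± 0.08 (SD of array medians, n = 2). There the NPC marks were at 0.28 for H3K4me1, 0.20 for H3K4me2 and 0.38 for H3K4me3, against 0, 0.01 and 0 elsewhere. Each of these medians exceeded all 1000 circular shifts. In the same windows the ES medians of these marks, 0.065, 0.095 and 0.065, did so too. The shifts therefore do not tell marks at NPC CHD7 windows from a background shared by the arrays. Of these windows, 136 (32.3%) had H3K4me3 in its top 5% and 146 (34.7%) had H3K4me1 without H3K4me3. They shared 35 windows with the ES sites, where independent lists would share 6.05 and the circular shifts shared up to 17. This list was ranked by ratio alone, chosen because the called list was empty. With only the 2 NPC arrays in the fit 113 windows were enriched and 166 depleted, trended and robust moderation gave 43 and 7, and the enriched count was 49 without ES replicate 2 and 4 without NPC replicate 2. On NPC replicate 2 alone, the H3K4me3 median in its top 1% was 0.70 above that elsewhere. Of 100 windows raised in simulated NPC arrays, 0% were recovered at a shift of 0.75 and 99% at 1.5, a share that depends on how many windows are raised.

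Across NPC windows CHD7 had r = 0.56 with H3K4me1, 0.49 with H3K4me2 and 0.67 with H3K4me3, and rho of 0.59, 0.54 and 0.70. For H3K4me2, r was 0.32 without NPC replicate 2 and 0.23 with each probe by itself. With the ES arrays of the same marks, r was 0.01, 0.12 and 0.18. The ES CHD7 mean had r = 0.41, 0.59 and 0.50 with the NPC arrays of the marks. High r with the NPC mark arrays was thus not particular to CHD7 in NPC.

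**Figure D3:**
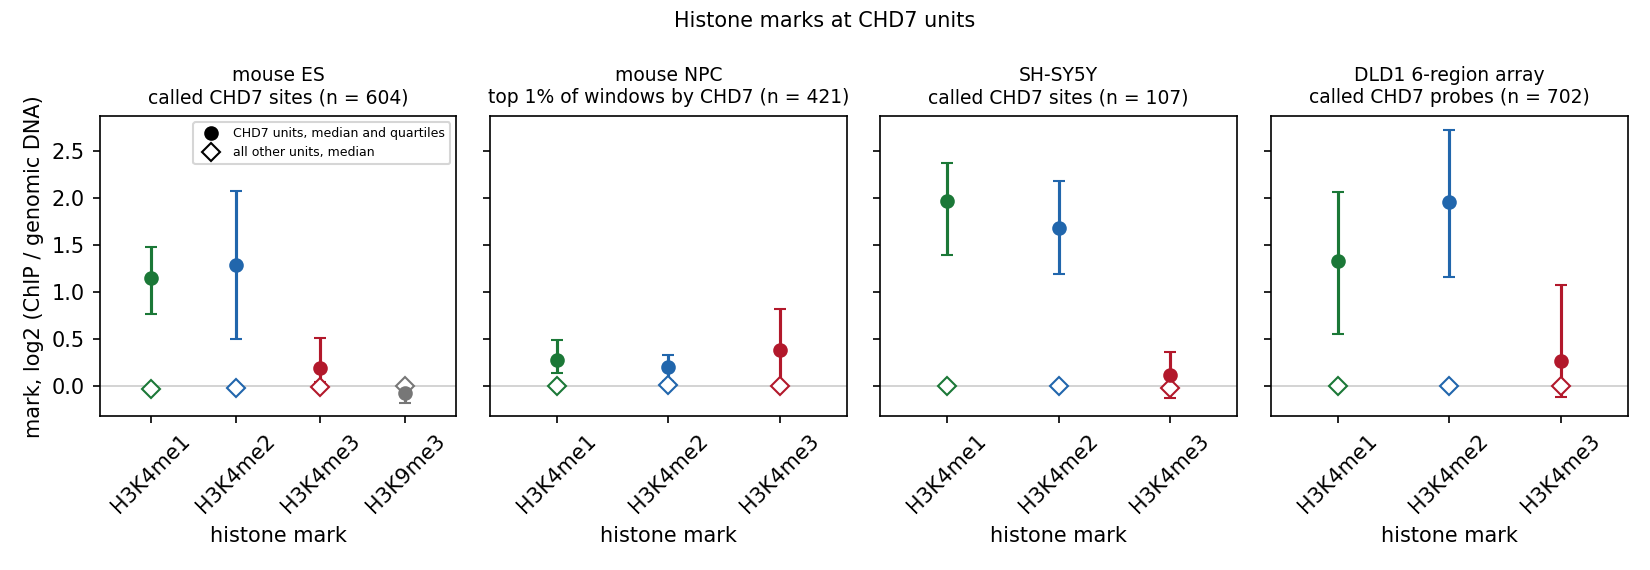
Log2 ratio of each histone mark (1 array each) at CHD7 units, as median with quartiles, and at all other units, as median, for 604 ES sites, the 421 top NPC windows, 107 SH-SY5Y sites and 702 DLD1 probes. H3K4me1 and H3K4me2 are at 1.15 and 1.28 in ES, 1.97 and 1.68 in SH-SY5Y and 1.32 and 1.96 in DLD1, while H3K4me3 lies between 0.12 and 0.38 in the 4 panels.

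The next comparison asked how CHD7 and the marks changed from ES cells to NPC. Of the 604 windows enriched in ES cells, CHD7 fell in 489, which merged to 358 regions, and rose in 0, with 528 at an unadjusted p under 0.05 by limma. At the 604 sites the NPC arrays had a median CHD7 ratio of 0.02 ± 0.01 (SD of array medians, n = 2). On chromosome 10 from 85993001 to 85993500, CHD7 fell by 1.94 on the log2 scale, from 1.53 ± 0.26 (SD, n = 3) to -0.41 ± 0.03 (SD, n = 2), while H3K4me1 went from 1.74 to -0.57. In the region on chromosome 9 from 78444501 it fell by 1.93, and in that on chromosome 6 from 15653501 by 1.92. Over the 489 windows the median of H3K4me1 went from 1.19 to 0.08, that of H3K4me2 from 1.30 to 0.00 and that of H3K4me3 from 0.20 to -0.09. H3K4me1 was lower in NPC in 95.5% of these windows, H3K4me2 in 92.8% and H3K4me3 in 84.3%. Of all windows, these shares were 46.2%, 47.6% and 48.2%. All windows are not a matched baseline, since the windows where CHD7 fell had higher medians of each mark on the ES arrays than the rest. The upper tail of each mark was also lower on its NPC array. Windows of equal ES mark level were not compared, so these shares do not show that marks were lost where CHD7 fell. Over the 604 sites the CHD7 and mark changes had r = 0.33 for H3K4me1, 0.32 for H3K4me2 and 0.32 for H3K4me3. Over all windows these were 0.10, -0.12 and -0.13, so that the values for H3K4me2 and H3K4me3 changed sign. After scaling the arrays, the value for H3K4me3 over the sites was 0.15.

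The test was limma's, with Benjamini-Hochberg adjustment over the 604 windows, which were chosen on the same ES arrays and so lean towards a fall. The number of windows tested changed with each array left out. Without ES replicate 1, 93 of 95 tested windows were called. Without ES replicate 2, 808 of 1027 were called, and CHD7 rose in 34 of the 808. Without NPC replicate 2, 255 of 738 were called, and CHD7 rose in 3 of the 255. In sites called without 1 ES array, the array left out had a median of 1.67, 0.42 or 0.75 for replicates 1, 2 and 3, and NPC medians lay between -0.03 and 0.11. Tested over all windows, CHD7 fell in 65 and rose in 2, which form 1 region on chromosome 16 from 91356001 to 91357000. This region was chosen after its values were seen. There CHD7 was at -0.36 ± 0.32 (SD, n = 3) in ES and 1.36 ± 0.33 (SD, n = 2) in NPC.

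**Figure D4:**
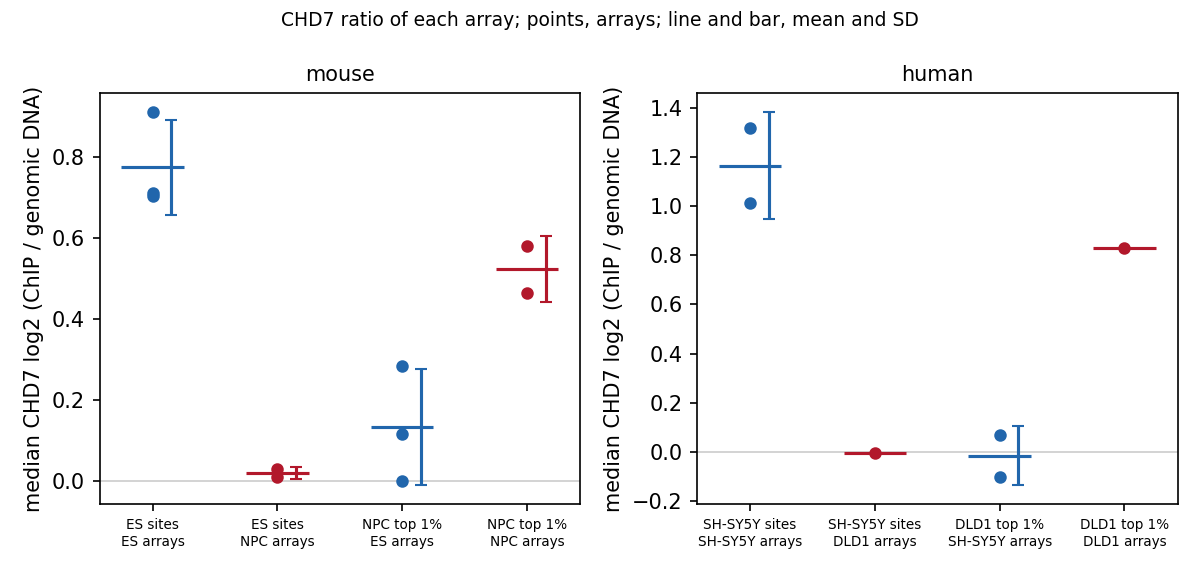
Median CHD7 log2 ratio of each array (points) with mean and SD (line and bar, no bar for the single DLD1 array) in windows called in ES or SH-SY5Y cells and in the top 1% of windows by CHD7 in NPC or DLD1. At ES sites the 3 ES arrays sit between 0.70 and 0.91 and the 2 NPC arrays at 0.01 and 0.03, and at SH-SY5Y sites the SH-SY5Y arrays sit at 1.01 and 1.32. Windows chosen on an array read high on that array.

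In SH-SY5Y cells CHD7 was enriched in 204 of 40271 windows, in 154 regions, with a median of 1.16 ± 0.22 (SD of array medians, n = 2). The region with the highest mean was on chromosome 16 from 61301001 to 61301500, with CHD7 at 2.35 ± 0.40 (SD, n = 2), H3K4me1 at 1.66 and H3K4me2 at 2.88. On chromosome 20 from 33509501 to 33510000 CHD7 was at 1.93 ± 0.58 (SD, n = 2), H3K4me1 at 2.46 and H3K4me3 at 0.78. Of the 10 highest regions 4 were on chromosome 7, where the bounds of both human tables did not match. Marks could be read in 30 of 45 segments, which held 107 of the called windows. At these, H3K4me1 had a median of 1.97 against 0 elsewhere, H3K4me2 1.68 against 0, and H3K4me3 0.12 against -0.03. The H3K4me1 and H3K4me2 medians exceeded all 1000 circular shifts and the H3K4me3 median 99.5% of them. In the top 1% of DLD1 windows the SH-SY5Y H3K4me1 median, 0.20, also exceeded all shifts. Of the 107 windows, 73 (68.2%) had H3K4me1 in its top 5% without H3K4me3 and 7 (6.54%) had H3K4me3. Of all windows in the matched segments, these shares were 4.07% and 5.02%. Across 23506 windows CHD7 had r = 0.29 with H3K4me1, 0.26 with H3K4me2 and 0.13 with H3K4me3, and rho of 0.21, 0.25 and 0.14. Without SH-SY5Y replicate 1 these r were 0.41, 0.40 and 0.24, and without replicate 2 they were 0.13, 0.09 and 0.01. With means in place of medians the H3K4me3 difference at sites was 0.02 in place of 0.14. The limma calls with Benjamini-Hochberg adjustment rested on 1 residual degree of freedom. They fell to 0 with trended and robust moderation, where 5563 windows had an unadjusted p under 0.05, and rose to 562 after scaling the arrays, with 1057 depleted windows in place of 154.

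SH-SY5Y cells (n = 2) and DLD1 cells (n = 1) were compared on the ENCODE array. Over all 40271 windows no difference passed limma's test after adjustment, and 2311 windows had an unadjusted p under 0.05. Over 610 windows chosen for a high ratio, those called in SH-SY5Y or in the top 1% of the DLD1 array, 198 passed the threshold with the higher ratio in SH-SY5Y and 337 with the higher ratio in DLD1, in 149 and 262 regions. This choice sets the direction for the most part, so these counts do not show that the cell lines differ. In the region on chromosome 16 from 61301001, SH-SY5Y was at 2.35 ± 0.40 (SD, n = 2) and DLD1 at -0.03. On chromosome 8 from 118892501 to 118893000 DLD1 was at 1.95 and SH-SY5Y at -0.63 ± 0.00 (SD, n = 2). Of the SH-SY5Y sites 6 of 204 were in the DLD1 top 1%, where independent lists would share 2.09 and the circular shifts shared up to 8. In the 103 windows of these with the higher ratio in SH-SY5Y that could be matched, SH-SY5Y H3K4me1 had a median of 1.98 and H3K4me2 of 1.68. In the 194 such windows with the higher ratio in DLD1 these were 0.12 and -0.03. SH-SY5Y H3K4me3 was at 0.12 in the first set and -0.15 in the second. Marks of DLD1 cells were measured only on the 6-region array, whose probe names give no positions and could not be matched to these windows. The values therefore do not describe marks in DLD1. The test assumed that the single DLD1 array varied like the SH-SY5Y arrays. With trended and robust moderation, which left no called SH-SY5Y window to test, 0 chosen windows passed with the higher ratio in SH-SY5Y and 316 with that in DLD1, with 327 of 412 tested windows at an unadjusted p under 0.05. After scaling the arrays these were 370 and 407.

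On the 6-region array of DLD1 cells, the FLAG and CHD7 antibodies were compared probe by probe, since the probe names give no positions. The CHD7 antibody enriched 702 of 43102 probes and the FLAG antibody 2724, with 71 and 1591 depleted, and 699 probes were in both lists, where independent lists would share 44.4 and the circular shifts along the probe order shared a median of 42 and up to 559. At the 702 probes the CHD7 antibody had a median of 1.91 ± 0.58 (SD of array medians, n = 3) and the FLAG antibody 2.23 ± 0.44 (SD of array medians, n = 3). The highest probe in both lists was A_17_P05378758, at 3.56 ± 0.76 (SD, n = 3) with the CHD7 antibody and 4.05 ± 0.55 (SD, n = 3) with FLAG. No probe differed between the antibodies with limma after adjustment, and 1934 had an unadjusted p under 0.05. Of 100 probes raised in simulated FLAG arrays, the difference was recovered in 0% at a size of 1.5 and in 67% at 3, a share that depends on how many probes are raised. The mean ratios of both antibodies had r = 0.77 and rho = 0.68 over probes, which does not exclude a part from genomic DNA shared by the arrays.

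At the 702 probes H3K4me1 had a median of 1.32, H3K4me2 of 1.96 and H3K4me3 of 0.26, against 0 elsewhere, and each exceeded all 1000 circular shifts. At the 2724 FLAG probes these were 0.90, 1.93 and 0.77. Of the 702 probes, 205 (29.2%) had H3K4me1 in its top 5% without H3K4me3, 146 (20.8%) had H3K4me3 and 316 had none. The H3K4me3 difference was 0.57 with means in place of medians and 0.01 at the top 1% of probes by CHD7. Across probes the CHD7 antibody had r = 0.44 with H3K4me1, 0.53 with H3K4me2 and 0.39 with H3K4me3, and rho of 0.32, 0.39 and 0.37. The lists lay close to the threshold, with limma adjusted p = 0.0302 for the highest CHD7 antibody probe and adjusted p = 0.0106 for the highest FLAG probe. CHD7 antibody calls fell to 0 without centring and without any 1 of its own arrays or FLAG replicate 1 or 2, with 5755 to 9091 probes at an unadjusted p under 0.05 in limma, and to 331 without FLAG replicate 3. FLAG calls fell to 0 without FLAG replicate 1 or 2, with 10420 and 9422 probes at an unadjusted p under 0.05, and to 1591 without FLAG replicate 3, and to 1687 and 1727 without CHD7 antibody replicates 1 and 3. These ratios take the deposited values as log10, a base the labels do not state, and as log2 the counts were 452 with the CHD7 antibody and 830 with FLAG. After scaling the arrays they were 1511 and 1692.

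**Figure D5:**
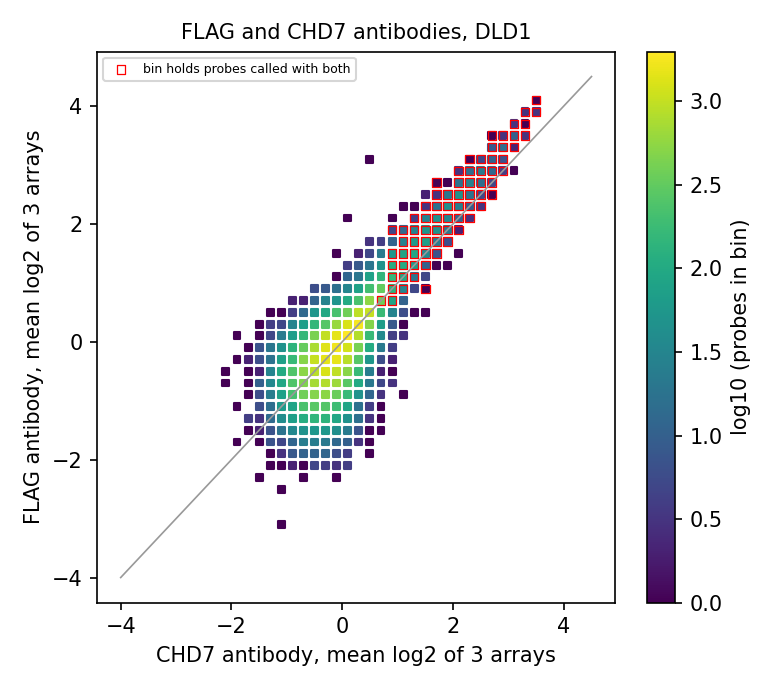
Mean log2 ratio of the FLAG antibody (3 arrays) against that of the CHD7 antibody (3 arrays) for 43102 probes in bins of 0.2, with colour for the log10 number of probes and red outlines for bins that hold any of the 699 probes called with both. The outlined bins lie at high ratios of both antibodies, up to the probe at 3.56 and 4.05; the grey line marks equal ratios.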

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

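The tests of the spread between arrays, of the mark tails, of the ratio of FLAG to CHD7 antibody counts after scaling, of the probes called with FLAG alone, of other splits of the arrays and of SH-SY5Y against DLD1 over all windows were chosen only after the result was seen. CHD7 differed between ES cells and NPC in 489 of the 604 windows tested, by limma's test of the difference over windows chosen on the same ES arrays, and in 67 when tested over all windows. Between the 2 SH-SY5Y arrays and the single DLD1 array, 535 of 610 windows passed the same test, but these were chosen for high ratios on the arrays tested. Over all windows 0 passed in limma, with 2311 at an unadjusted p under 0.05, so a difference between these cell lines is not shown.

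No NPC window passed limma's test with a spread shared with the ES arrays (1548 at an unadjusted p under 0.05) while 604 ES windows did, but 113 passed with only the NPC arrays in the fit and 43 with trended and robust moderation. A larger spread between NPC arrays is argued against, since the median SD between the NPC arrays was 0.391 of that between the ES arrays. These medians were 0.09 for 2 NPC arrays and 0.24 for 3 ES arrays, and a median SD over fewer arrays tends to read lower. The wider ES spread entered the shared fit, so the empty NPC list may rest in part on it. Without ES replicate 2, 49 NPC windows passed, and without ES replicate 1 or 3, 0 did. Lower enrichment in all NPC immunoprecipitates stays open, since the ratio exceeded by 1 in 1000 windows was lower in NPC for each H3K4 mark, with a difference of -0.77 for H3K4me1, -2.34 for H3K4me2 and -1.87 for H3K4me3. The changes of CHD7 and H3K4me2 over the ES sites had rho = 0.31, above the 95th percentile of the shifts at 0.08, which CHD7 leaving windows that lose H3K4me2 would give. NPC arrays with no signal would give it as well, since the ES levels alone had rho = 0.33, so a biological change and weak NPC immunoprecipitates cannot be told apart.

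CHD7 correlated with all H3K4 marks over NPC windows. A background shared by the arrays is a candidate explanation. In NPC, r with H3K4me3 was 0.70 in the 35904 windows outside the top 5% of CHD7 and of each mark. Over all windows it was 0.67. Outside the top 5%, r was 0.62 for H3K4me1 and 0.49 for H3K4me2 in NPC. In ES cells r with H3K4me3 was 0.02 over all windows and 0.23 outside the top 5%, where it was 0.02 for H3K4me1 and 0.07 for H3K4me2. With the NPC array of H3K4me3, ES CHD7 replicates 2 and 3 had r of 0.50 and 0.57, and replicate 1 had -0.08. Such a background may thus not be limited to the NPC arrays. CHD7 at H3K4me3 peaks was not decided: the top 1% of H3K4me3 windows minus the next 9% differed by -0.0575 in CHD7, with the NPC arrays at 0.12 and -0.23.

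FLAG called 2724 probes and the CHD7 antibody 702. After scaling the arrays to a common spread the ratio of these counts was 1.12, so a difference in array scale may account for the gap. The 2025 probes called with FLAG alone had a median CHD7 antibody ratio of 0.78, and 99.5% of them lay above 0 with it. Most of these probes were thus raised with both antibodies. FLAG binding where CHD7 is missing is not decided by this, since a background shared by the arrays would raise both. The antibody comparison called 0 probes, as did each of the 10 splits of the 6 arrays into 3 and 3, with 0 as the highest of the others, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 in limma the comparison had 1934 probes and the 9 other splits had 1585 to 4790, with more than 1934 in 3 of them.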

How the results depend on the processing

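The handling of zeros, the base of the logarithm, the running median, the test of SH-SY5Y against DLD1 over all windows and all NPC values at the top 1% of windows were chosen only after the data were seen. Of the alternatives, 143 left a result within its spread or within 1.5 times its count, and 73 moved it further. The other 2 turned the sign of a value larger than its spread. Both were correlations of CHD7 and mark changes over all windows in place of ES sites, at -0.12 for H3K4me2 and -0.13 for H3K4me3. For H3K4me1 this gave 0.10. Smaller values that changed sign were not counted as turned. Without ES replicate 3, r of CHD7 and H3K4me2 over ES windows went from 0.10 to -0.05. That of H3K4me3 went from 0.02 to -0.13, and to -0.01 without ES replicate 1. These r lay below their spread between single ES arrays, 0.31 and 0.27, so staying within the spread says little for them. The cause was not tested, here or for the other moves below, except where fewer arrays were used.

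Means in place of medians put the difference between CHD7 units and others at 1.02 for ES H3K4me1, 0.35 and 0.245 for NPC H3K4me1 and H3K4me2, 1.68, 1.56 and 0.0196 for SH-SY5Y H3K4me1, H3K4me2 and H3K4me3, and 0.57 for DLD1 H3K4me3. The top 1% of units by CHD7 gave 1.61 and 0.16 for SH-SY5Y H3K4me2 and H3K4me3, and 1.69, 2.12 and 0.0133 for DLD1 H3K4me1, H3K4me2 and H3K4me3. Single probes put r in NPC at 0.46, 0.23 and 0.52 for H3K4me1, H3K4me2 and H3K4me3. Scaled arrays put the correlation of CHD7 and H3K4me3 changes at 0.15.

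Counts of ES windows were 147 with a minimum ratio of 1, 252 with windows of 1000 bp and 6397 with single probes. Counts of NPC windows were 5 without centring, 2 after scaling, 43 with trended and robust moderation, 306 with single probes and 113 with only NPC arrays in the fit. Windows that differed between NPC and ES cells numbered 67 over all windows, 111 with a minimum of 1, 206 with windows of 1000 bp and 5078 with single probes, of which 264 rose; of 628 with trended and robust moderation 40 rose. SH-SY5Y windows numbered 562 after scaling, 0 with trended and robust moderation in limma (5563 at an unadjusted p under 0.05) and 1533 with single probes. Those that differed from DLD1 numbered 0 over all windows in limma (2311 at an unadjusted p under 0.05), 305 with a minimum of 1, 316 with trended and robust moderation and 4225 with single probes. On the 6-region array, counts for the CHD7 antibody and FLAG were 1511 and 1692 after scaling, 1333 and 4192 with trended and robust moderation, 452 and 830 as log2 values, and 2506 and 4114 with a running median. Without centring the CHD7 antibody gave 0 in limma (9091 at an unadjusted p under 0.05).

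With 1 array left out at a time, counts ran from 95 to 986 in ES cells, 0 to 49 in NPC, 93 to 808 for the change between them, 0 to 331 with the CHD7 antibody and 0 to 2321 with FLAG. In these, r ran from 0.0352 to 0.40 for ES H3K4me1, -0.0466 to 0.42 for ES H3K4me2, 0.46 to 0.54 for NPC H3K4me1, 0.32 to 0.54 for NPC H3K4me2, 0.49 to 0.69 for NPC H3K4me3 and 0.32 to 0.39 for DLD1 H3K4me3. Mark differences ran from -0.105 to -0.08 for ES H3K9me3, 0.245 to 0.285 for NPC H3K4me1 and 0.30 to 0.70 for NPC H3K4me3. A lone array was assumed to vary like the other group.

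Same-numbered FLAG and CHD7 antibody arrays had deviations correlated at 0.01, 0.12 and 0.21, and not every array correlated best with its own number; for ES and NPC arrays these values were 0.45 and 0.34, with 2 shared numbers, which are too few to pair the samples here, and with the 2 NPC arrays opposite to each other by construction. With the replicate block the change from ES cells to NPC was called in 491 windows, in place of 489. The antibody difference was called in 0 probes of limma's test (2324 at an unadjusted p under 0.05). The block thus changed these counts little. Over all windows, those at an unadjusted p under 0.05 in limma for the change between ES cells and NPC rose from 2186 to 6151. Adjusted calls over all windows were not run with the block. The antibody difference stayed at 0 called probes in each of its 15 alternatives.

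Without the DLD1 array the count in SH-SY5Y was 204 again, since a lone array adds nothing to the spread. Sites of SH-SY5Y with 1 of its own arrays left out were not run, since no residual degree of freedom is left. There was no value for marks at called NPC sites, since none was called, or for marks at CHD7 antibody sites without 1 of its arrays, since none was called. Windows of 1000 bp do not apply to the 6-region array, and single probes do not match between both human tables with positions. Among the 604 windows tested for a change from ES cells to NPC none rose in CHD7, so marks could not be read there. The number of arrays limits the precision of all these counts.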

Other observations

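The levels, shares and correlation in this part were chosen only after the data were seen and carry no test, while the counts of depleted windows come from limma fits fixed in advance. In ES cells the top 1% of windows by H3K4me3 had a median CHD7 ratio of -0.23, against 0.05 elsewhere, those by H3K9me3 had -0.14 against 0.05, those by H3K4me2 had 0.00 and those by H3K4me1 had 0.13. Single ES arrays of CHD7 differed in sign over all windows, with r of 0.10, -0.20 and 0.33 with H3K4me3 for replicates 1, 2 and 3. In SH-SY5Y the top 1% by H3K4me1 had a CHD7 ratio of 0.39, with a CHD7 site in 40 of 239 windows, while 3 of 236 top H3K4me2 windows and 0 of 236 top H3K4me3 windows held one. Around ES regions, the mean CHD7 ratio was 0.88 at the centre and 0.23 at 1000 bp to its right, where H3K4me1 was at 1.07 and 0.66. The centre was chosen as the highest CHD7 window, which by itself gives a fall of CHD7 away from it. The widths of CHD7 and H3K4me1 can thus not be compared here.

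The 532 windows where CHD7 lay below genomic DNA in ES cells had H3K4me2 at -0.75 and H3K4me3 at -0.79 on the NPC arrays, and at -0.15 and -0.23 on the ES arrays. Their CHD7 median was -0.45, -1.35 and -0.57 on ES replicates 1, 2 and 3, and with trended and robust moderation only 10 windows were depleted. At the ES sites the NPC levels of CHD7 and H3K4me2 had rho = 0.55, beside 0.54 over all NPC windows. This value was thus not particular to the ES sites.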
